A study of Nicotiana tabacum with 16 samples.

How the data were processed

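Root RNA of Nicotiana tabacum was sequenced in 16 libraries of 4 genotypes: K326, nic1 nic2, myc2a and nic1 nic2 myc2a, the last 3 in the K326 background. Per the labels' protocols, plants were grown in a greenhouse in pots standing in water, 3 to 5 per genotype, and topped at flowering. Roots were collected 18 h later from each plant. RNA was purified with a Qiagen RNeasy plant kit, and libraries were made with the NEBNext Ultra Directional kit. Per the submitters' processing notes, FastQC, HISAT2 2.1.0, SAMtools and bedtools were used. The genome build, the annotation and the counting settings were not given in the sources used here.

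The deposited table held a count per gene model and library, with 63697 gene models, of which 13428 were at 0 in every library. The values were checked to be whole numbers. Between 59.7 and 65.6% of the low counts (1 to under 200) were even, an excess over odd ones, so the mates of a pair seem to have been counted separately and a count is not a number of fragments. Columns were assigned to libraries by their names. The columns of the genotype nic1 nic2 myc2a had their letters in another order than the sample titles and were matched by genotype letters and number. There were 0 unused columns.

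The gene identifiers consist of an ID group (1 to 24, and a group without number) and a serial number. That serial numbers follow the order on chromosomes is not stated in the sources used here. Of the identifiers, 0 matched the reference table of gene symbols, so genes are given by identifier. The 21 gene lists fixed before the data were examined, on nicotine synthesis, ERF and jasmonate genes among others, were not analysed here for that reason.

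Counts were analysed in R 4.3.3 with edgeR 4.0.16. Gene models were filtered with filterByExpr at its defaults, which left 43009. Libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model with 1 mean per genotype was fitted to all 16 libraries, with 12 residual degrees of freedom, and P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were each recessive genotype against K326, nic1 nic2 myc2a against nic1 nic2 and against myc2a, and the interaction. These comparisons, the threshold, the rule for naming genes and the alternatives other than those stated below were chosen before the data were examined. The rule names the largest rises and falls, a pair in each direction, of each comparison with K326 among called gene models with a mean of at least 2 CPM in the higher group and no overlap between the libraries of both groups. Other gene models are said to be chosen after their values were seen. Levels are CPM on TMM-scaled library sizes, with mean and SD over libraries. Folds against a group without counts are bounds computed with 3 counts per library in that group. Log2 CPM used a prior count of 2.

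Total counts per library ranged from 32.2 M to 71.8 M. The procedure was tested on simulated data with the real group sizes and depths, with 100 gene models changed 2-fold and 100 changed 4-fold among 43009. For nic1 nic2 against K326, 28% of the 2-fold and 70% of the 4-fold changes were recovered, for myc2a 42% and 74%, and for nic1 nic2 myc2a 43% and 77%. For nic1 nic2 myc2a against nic1 nic2 the shares were 30% and 79%, against myc2a 38% and 83%, and for the interaction 11% and 57%. False calls made up 0 to 5.47% of calls.

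Stretches of changed neighbours were searched after the data had been seen. In each library, the log2 ratio of CPM plus 0.5 to the median of all libraries was taken for gene models with a mean log2 CPM of at least 1. Running medians of 51 neighbouring gene models were compared with the largest absolute running median of 100 shuffles of the order. A stretch had to cover 51 windows. This minimum was raised from 20 after the hits were seen, which dropped a stretch of 34 windows in K326 replicate 2 (ID group 18, 17620 to 18300, median log2 ratio 0.54) and of 27 windows in K326 replicate 3 (ID group 11, 19190 to 19740, 0.23). On simulated data with 160 neighbouring gene models shifted by -1 or 0.58 on the log2 scale, 4 of 4 stretches were found at each shift, with 0 false ones in 4 unshifted data sets, with ratios taken to the median of all libraries. The simulated gene models varied independently and the raised minimum was used, so the false rate in the real libraries was not measured. Ends were refined within 60 gene models. The percent of K326 is 2 to the power of the median log2 ratio to the K326 mean. Nearly absent gene models were those called, at least 16-fold lower and under 0.5 CPM in every library of the genotype. Runs joined nearly absent gene models with serial numbers at most 100 apart.

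Sets of gene models were scored by their mean log2 CPM per library and compared by exact two-sided permutation of libraries. The sets were defined after the data had been seen. For the overlaps of calls, 20 simulated data sets without changes kept the shared K326 libraries, and the K326 libraries were also split into separate pairs in 6 ways.

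Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1) with sample quality weights, relative log expression (RLE) size factors, library size only, no filter, a filter of 1 CPM in 3 libraries, and only the compared groups. Others were calls of at least 2-fold, overlaps at an adjusted p of 0.01, a factor for replicate number and leaving out each library. Added after the data were seen were the thinning of K326 replicate 2 to the depth of the other K326 libraries, leaving out K326 replicate 2 and nic1 nic2 replicate 3 together, counting only outside the stretches and runs, the overlaps with nic1 nic2 myc2a, and leaving out single libraries for the overlaps. No library was left out of the main analysis.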

Results

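Root transcriptomes of tobacco (Nicotiana tabacum) were measured by RNA sequencing in the cultivar K326 and in 3 nearly isogenic genotypes with recessive alleles at Nic1 and Nic2, at Myc2a, or at all of these loci. The Nic loci control the nicotine content of the plant, and Nic2 holds a cluster of ERF transcription factor genes. MYC2a is a bHLH transcription factor of jasmonate signalling. Nicotine is made in roots, and topping, the removal of the shoot apex, stimulates its synthesis. Roots were collected 18 h after topping from pot-grown plants. The question, per the series' design text, was how root expression differed between genotypes at these loci. There were 16 libraries: 4 of K326, 3 of nic1 nic2, 5 of myc2a and 4 of nic1 nic2 myc2a. Total counts lay between 32.2 M and 40.9 M per library, except for K326 replicate 2 with 71.8 M. The labels speak of collection from each plant but do not state that each library was a separate plant, so the p-values measure the spread between these samples.

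Gene models carried identifiers of an ID group and a serial number, such as Ntab24g014090-1.1, with no gene names. The ERF genes of Nic2, MYC2a and the genes of nicotine synthesis were therefore not analysed here by name, and the targeted genes could not be used to check the labels. Results are given by identifier and by stretches of neighbouring serial numbers, as the order in the table and not as chromosome positions. The first principal component of the 1000 most variable gene models held 24.5% of the variance and the second 15.6%. Both genotypes with nic1 nic2 lay on the positive side of the first component (4.8 to 48.4), and the K326 and myc2a libraries on the negative side (-33.2 to -5). The library nic1 nic2 replicate 3 stood apart on the second component (73.8), with a mean Spearman correlation of 0.946 to its own group and 41283 detected gene models, the fewest of the 16 libraries.

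In nic1 nic2 roots, a stretch of neighbouring gene models in ID group 18 was lower than in K326. Between serial numbers 18660 and 22210, the median of 198 gene models was 53.4, 52.8 and 51.1% of the K326 level in nic1 nic2 replicates 1, 2 and 3, and 98.5% of these gene models were lower than in K326. The same stretch was at 98.7% or more in each of the 5 myc2a libraries and at 99.3 to 103% in the 4 nic1 nic2 myc2a libraries. In ID group 24, 8 gene models between 14040 and 14150 were nearly absent: their summed count fell from 130 ± 17.4 CPM (counts scaled to a common library total; SD, n = 4) in K326 to 0.376 ± 0.178 (n = 3), and was 106 ± 16.3 (n = 4) in nic1 nic2 myc2a. Of these, Ntab24g014090-1.1 had no counts in any nic1 nic2 library and was at least 127-fold lower than in K326 (11.0 ± 2.06 CPM). Ntab24g014140-1.1, also without counts in nic1 nic2, was at least 109-fold lower (9.46 ± 0.657 CPM in K326).

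The largest rises in nic1 nic2 were in Ntab14g014280-1.1, with a log2 fold change of 8.01 ± 1.19 (SE; edgeR adjusted p = 0.00218), and Ntab17g010270-1.1, with 6.04 ± 0.96 (edgeR adjusted p = 0.00389). Their levels differed widely between replicates: Ntab14g014280-1.1 was at 0.605, 6.78 and 16.4 CPM in nic1 nic2 replicates 1, 2 and 3, against 0.0271 ± 0.0223 CPM in K326 (SD, n = 4), and Ntab17g010270-1.1 at 0.877, 19.9 and 41.2 CPM. Over 26 alternatives the adjusted p of Ntab14g014280-1.1 ranged from 2.27e-10 to 0.106 and that of Ntab17g010270-1.1 from 1.77e-07 to 0.18, with both calls lost under limma-voom with sample quality weights. Both were also lost without K326 replicate 2 and nic1 nic2 replicate 3 together (adjusted p = 0.074 and 0.0822). Under limma-voom with sample quality weights the call of Ntab24g014090-1.1 was also lost (adjusted p = 0.0631, range 4.65e-16 to 0.0631), although its level in nic1 nic2 was 0 in each library.

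Of 43009 gene models tested with edgeR's quasi-likelihood test, 395 differed between nic1 nic2 and K326 at an adjusted p of 0.05, 146 higher and 249 lower. Of these, 111 lay in the stretch of ID group 18, 12 in runs of nearly absent gene models and 270 outside all such stretches and runs (146 higher, 124 lower). With library size as the only scaling the split was 269 higher and 204 lower, so the excess of falls depended on the scaling. The count moved by over 1.5 times without K326 replicates 1 (37 higher, 162 lower), 2 (43 higher, 136 lower), 3 (226 in all) or 4 (184), without nic1 nic2 replicates 1 (669), 2 (196) or 3 (173), and without myc2a replicate 5 (746). Without both K326 replicate 2 and nic1 nic2 replicate 3 it was 119, and DESeq2 called 1997.

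**Figure D1:**
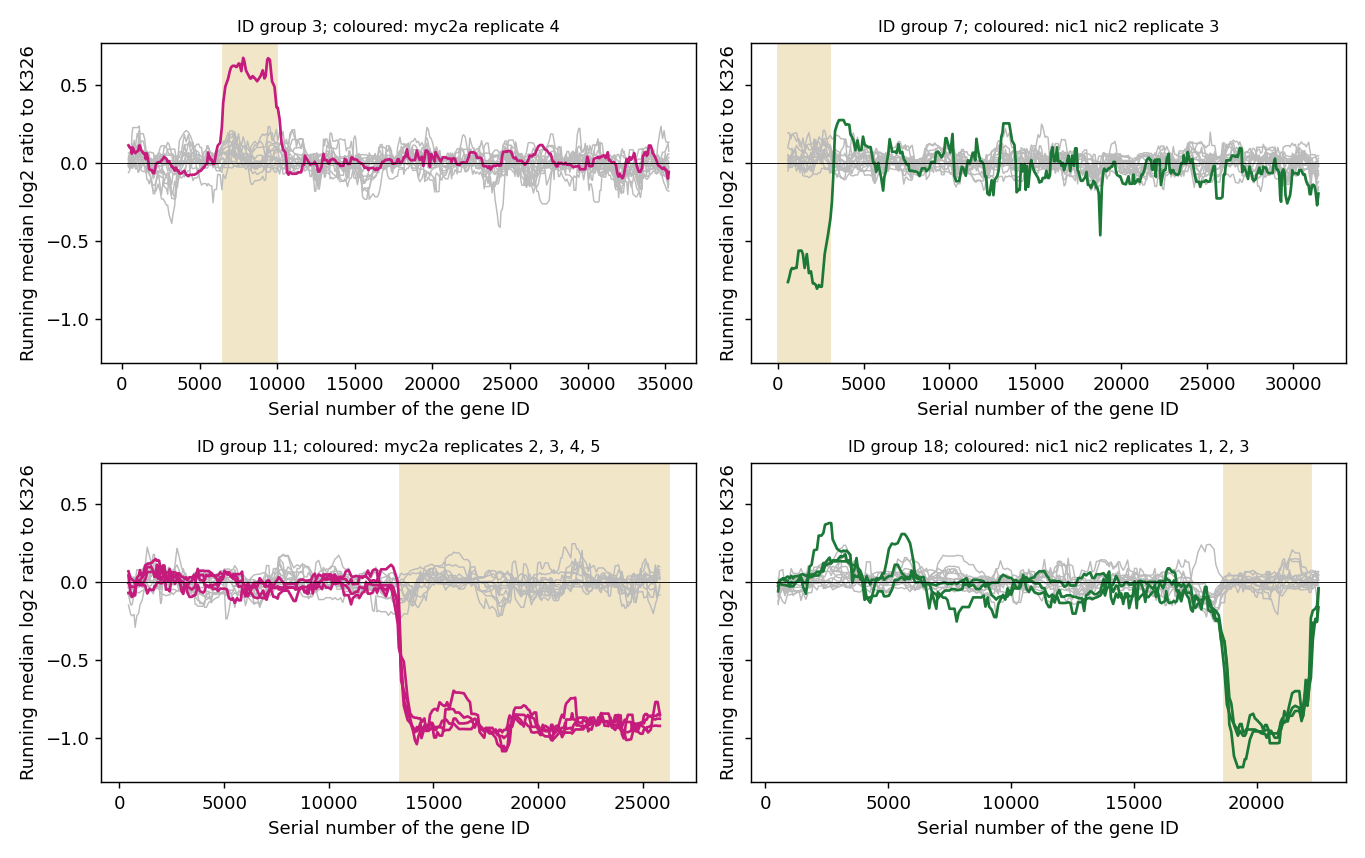
Running median over 51 gene models of the log2 ratio to the K326 mean (vertical axis) against the serial number of the gene identifier (horizontal axis) in ID groups 3, 7, 11 and 18, with 1 line per library and the shaded stretch marked. Coloured lines are the libraries named in each panel; in ID group 11 they are myc2a replicates 2 to 5, at 52.6 to 54.2% of K326 in the shaded stretch, and in ID group 18 the 3 nic1 nic2 libraries, at 51.1 to 53.4%.

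In myc2a roots, a stretch of gene models in ID group 11 was lower than in K326 in 4 of the 5 libraries. Between serial numbers 13420 and 26250, the median of 657 gene models was 52.6, 52.6, 53.3 and 54.2% of the K326 level in myc2a replicates 2, 3, 4 and 5, but 99.2% in myc2a replicate 1. The same stretch was at 98.8 to 102% in the nic1 nic2 myc2a libraries, whose label also names myc2a. In ID group 8, 6 gene models between 28890 and 28950 were nearly absent in all 5 myc2a libraries, with a summed level of 0.252 ± 0.0999 CPM (SD, n = 5) against 74.5 ± 3.90 in K326 (n = 4) and 79.2 ± 2.50 in nic1 nic2 myc2a (n = 4). Among them, Ntab08g028910-1.1 had no counts in myc2a and was at least 147-fold lower than in K326 (11.8 ± 1.91 CPM). Ntab11g019640-1.1, inside the stretch of ID group 11, also had no counts in any myc2a library, replicate 1 included, and was at least 121-fold lower.

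Among the rises, Ntab17g006510-1.1 had no counts in the 4 K326, 3 nic1 nic2 and 4 nic1 nic2 myc2a libraries and 4.37 ± 2.24 CPM in myc2a (SD, n = 5), at least 61.3-fold higher than in K326 (edgeR adjusted p = 0.00381, range 6.26e-15 to 0.0671 over 26 alternatives). Ntab06g019820-1.1 rose by 5.22 ± 0.88 on the log2 scale (SE; edgeR adjusted p = 0.0205), from 0.124 ± 0.0752 CPM in K326 to 4.71 ± 3.98 in myc2a. That call was lost in 8 of 26 alternatives (largest adjusted p 0.362), among them those without K326 replicate 1 (0.088), 2 (0.132), 3 (0.083) or 4 (0.0793) and without myc2a replicate 2 (0.0501). Gene models outside the stretches and runs, chosen after their values were seen, included Ntab05g003880-1.1, which fell from 18.6 ± 1.81 CPM in K326 to 0.0955 ± 0.105 in myc2a (log2 fold change -7.55 ± 0.40, edgeR adjusted p = 9.85e-09). Ntab22g024750-1.1 fell from 17.3 ± 1.85 to 0.105 ± 0.189 CPM (log2 fold change -7.30 ± 0.50, edgeR adjusted p = 2.06e-07). In nic1 nic2 myc2a, Ntab05g003880-1.1 was at 31.1 ± 6.09 CPM and Ntab22g024750-1.1 at 18.2 ± 1.77 CPM (n = 4). Both were nearly absent in myc2a without being in a run, as were Ntab06g022330-1.1, Ntab10g022030-1.1 and Ntab20g007510-1.1.

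In all, 73 gene models differed between myc2a and K326, 14 higher and 59 lower. Of these, 42 lay in the stretch of ID group 11, 7 in runs and 23 outside (13 higher, 10 lower). The count moved by over 1.5 times without K326 replicates 1 (22), 2 (19), 3 (30) or 4 (30), without nic1 nic2 replicate 2 (46), without myc2a replicates 1 (434), 2 (31), 3 (37), 4 (32) or 5 (37), and without nic1 nic2 myc2a replicates 1 (43) or 4 (44). Without myc2a replicate 1, 388 of the 434 gene models lay in the stretch of ID group 11. Without both K326 replicate 2 and nic1 nic2 replicate 3 the count was 22.

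In nic1 nic2 myc2a roots, 5 gene models of ID group 19 between 19530 and 19610 were nearly absent. Their summed level was 0.127 ± 0.218 CPM (SD, n = 4), against 64.0 ± 3.02 in K326 (n = 4), 72.5 ± 10.4 in nic1 nic2 (n = 3) and 67.7 ± 6.42 in myc2a (n = 5). Within this run, Ntab19g019550-1.1 had no counts and was at least 126-fold lower than in K326, and Ntab19g019570-1.1, also without counts, at least 97.0-fold lower. Ntab06g019820-1.1 rose by 5.61 ± 0.90 on the log2 scale (SE; edgeR adjusted p = 0.00697, range 7.48e-07 to 0.0921), to 6.14 ± 3.73 CPM. Ntab19g031540-1.1 rose by 5.53 ± 0.45 (edgeR adjusted p = 2.95e-06), from 0.233 ± 0.127 CPM in K326 to 11.5 ± 2.77, and was at 12.8 ± 0.986 CPM in nic1 nic2. In all, 127 gene models differed from K326, 49 higher and 78 lower, of which 11 lay in runs, 1 in the stretch of ID group 11 and the others outside (49 higher, 66 lower). The split was 78 higher and 72 lower with library size only, and 499 higher and 488 lower with DESeq2. The count moved by over 1.5 times without K326 replicates 1 (67) or 2 (75), nic1 nic2 replicate 3 (201), myc2a replicate 1 (273) or nic1 nic2 myc2a replicates 2 (75), 3 (427) or 4 (73). Without both K326 replicate 2 and nic1 nic2 replicate 3 it was 82.

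**Figure D2:**
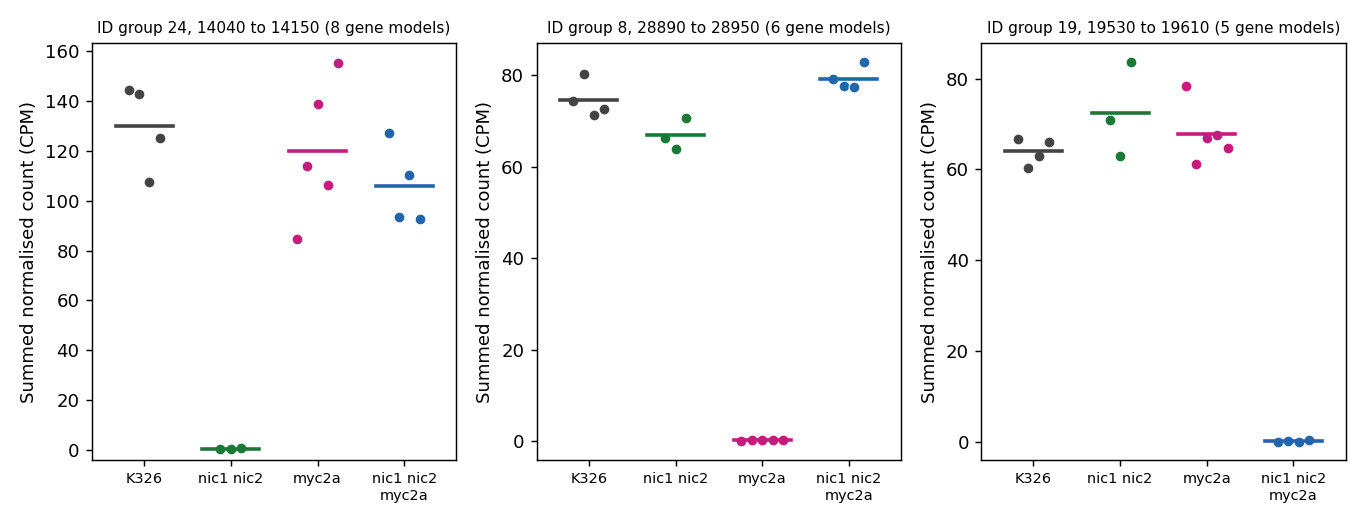
Summed normalised count in CPM (vertical axis, linear) of the nearly absent gene models of 3 runs in the 4 genotypes (horizontal axis); points are libraries and bars are means. Each run was near 0 in a single genotype: ID group 24 in nic1 nic2 (0.376 CPM), ID group 8 in myc2a (0.252 CPM) and ID group 19 in nic1 nic2 myc2a (0.127 CPM).

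Between both genotypes that carry nic1 nic2, 52 gene models were called against K326 in the same direction, 15 higher and 37 lower, and 0 in opposite directions. Of the 37 lower ones, 5 were nearly absent in both genotypes, and the other 32 are described as a set. The 32 gene models lay in 17 ID groups, and 21 of them exceeded 100 CPM in K326. Their summed level was 8782 ± 5561 CPM in K326 (SD, n = 4; 4970 to 17047), 1252 ± 71.2 in nic1 nic2 (n = 3), 1232 ± 233 in nic1 nic2 myc2a (n = 4) and 4337 ± 670 in myc2a (n = 5). The median log2 fold change was -3.45 in nic1 nic2 and -3.20 in nic1 nic2 myc2a, and 22 and 23 of the 32 were over 4-fold lower.

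Members of the set named here were chosen after their values were seen. Ntab06g021890-1.1 was at 923 ± 464 CPM in K326 (SD, n = 4) and 72.6 ± 12.4 in nic1 nic2 (n = 3), a log2 fold change of -3.67 (edgeR adjusted p = 1.84e-05). Ntab08g023550-1.1 had the largest fall in nic1 nic2, with a log2 fold change of -6.64 (edgeR adjusted p = 9.7e-05), from 432 ± 457 to 4.33 ± 1.97 CPM. Neighbouring serial numbers fell together in 8 pairs, among them Ntab12g015220-1.1, Ntab12g015230-1.1 and Ntab12g015240-1.1 (log2 fold changes -3.23, -5.17 and -4.52 in nic1 nic2). Whether neighbouring gene models share reads as near-identical copies was not analysed here, so such values are uncertain. Ntab19g031560-1.1, Ntab19g031570-1.1 and Ntab19g031580-1.1 fell (log2 fold changes -1.13, -1.12 and -1.12 in nic1 nic2) beside Ntab19g031540-1.1, which rose.

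The mean log2 level of the 32 gene models was lower by 3.20 in nic1 nic2 and by 3.40 in nic1 nic2 myc2a than in K326 (differences -3.20 and -3.40), each with an exact permutation p of 0.0286, the smallest possible. The set was chosen on these comparisons, so neither p is independent evidence. In myc2a the difference from K326 was -0.86 (two-sided exact permutation p = 0.0159), and 32 of 32 gene models were lower. The set was chosen for falls from these same K326 libraries, which favours a fall in myc2a too, so this p is not independent either. With gene models chosen on a pair of K326 libraries and myc2a compared with the other pair, the median log2 fold change lay between -0.31 and -1.84 over 6 splits. It was -0.31, -0.46 and -0.81 with K326 replicate 2 in the choosing pair, and -1.64, -1.73 and -1.84 with it in the compared pair. The difference of the set rested in part on K326 replicate 2, without which it was -0.53 (exact permutation p = 0.0536). edgeR called 0 of the 32 in myc2a, with 27 at an unadjusted p under 0.05; DESeq2 called 3 and limma-voom 4. The 15 gene models that rose in both nic1 nic2 genotypes had a summed level of 223 ± 15.3 CPM in K326, 428 ± 26.8 in nic1 nic2, 293 ± 32.4 in myc2a and 455 ± 54.0 in nic1 nic2 myc2a. In myc2a their mean log2 level was higher by 0.53 than in K326 (exact permutation p = 0.00794, the smallest possible), and edgeR called 2 of the 15. These gene models were chosen for rises from the same K326 libraries, which favours a rise in myc2a, and no split of K326 was run for them.

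**Figure D3:**
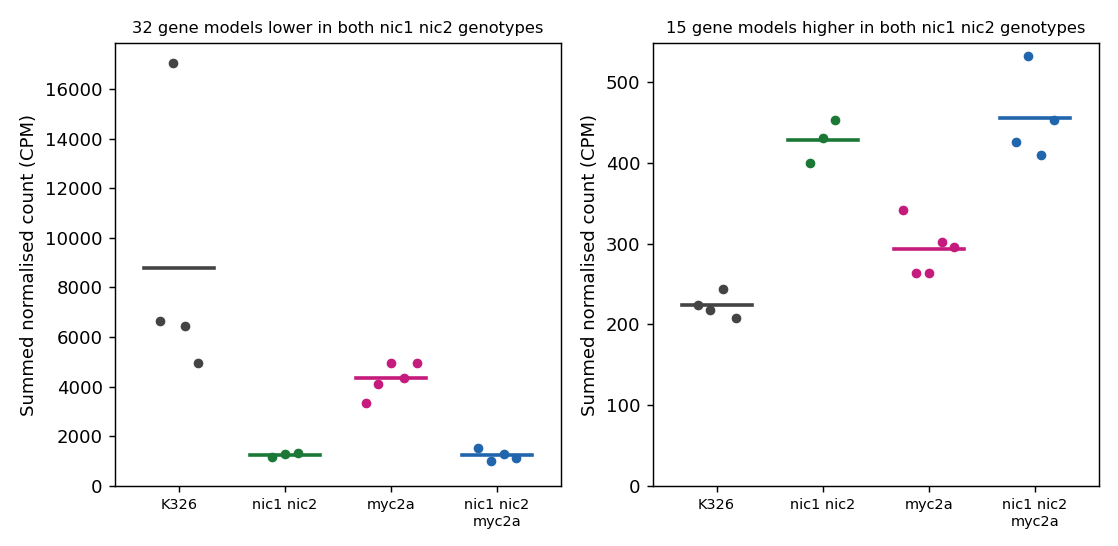
Summed normalised count in CPM (vertical axes, linear) of the 32 gene models lower and the 15 higher in both genotypes with nic1 nic2, by genotype (horizontal axis); points are libraries and bars are means. K326 replicate 2 lies at 17047 CPM in the lower set, above the other K326 libraries at 4970 to 6660 CPM.

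Where both lines carried nic1 nic2, nic1 nic2 myc2a was compared with nic1 nic2. The lines also differed in whole stretches and runs, so an effect of myc2a cannot be told apart from other differences between the lines. The stretch of ID group 18 was at 99.3 to 103% of K326 in nic1 nic2 myc2a and the run of ID group 24 at 81.5%, with both low in nic1 nic2, and the run of ID group 19 was nearly absent only in nic1 nic2 myc2a among the 4 genotypes. The set of 32 gene models differed little between these lines, by -0.20 on the log2 scale (two-sided exact permutation p = 0.543). edgeR and DESeq2 each called 0 of them, and 1 had an unadjusted edgeR p under 0.05. The set was chosen for falls in both of these lines, which favours a small difference, so this does not show that myc2a had no effect on it. In all, 174 gene models differed, 132 higher and 42 lower in nic1 nic2 myc2a. Of these, 97 lay in the stretch of ID group 18, 15 in runs, 2 in a stretch of ID group 7 and 60 outside (25 higher, 35 lower). DESeq2 called 361 higher and 277 lower. Without myc2a replicate 5, which shares only the estimate of the spread, the count was 291.

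Where both lines carried myc2a, nic1 nic2 myc2a was compared with myc2a. Of the set of 32 gene models, 26 were called lower, and the mean log2 difference was -2.54 (exact permutation p = 0.00794, the smallest possible), with nic1 nic2 myc2a part of the choice of the set. The run of ID group 8 was nearly absent in myc2a and the run of ID group 19 in nic1 nic2 myc2a. In all, 154 gene models differed, 79 higher and 75 lower, with 34 in the stretch of ID group 11, 18 in runs and 99 outside the stretches and runs (38 higher, 61 lower). The near-even split was not stable: it was 95 higher and 64 lower with library size only, 870 and 350 with limma-voom, 705 and 427 without myc2a replicate 1, and 106 and 245 without nic1 nic2 myc2a replicate 3. The count moved by over 1.5 times without myc2a replicates 1 (1132), 2 (80), 3 (73), 4 (73) or 5 (99) and without nic1 nic2 myc2a replicates 1 (74), 2 (72), 3 (351) or 4 (70).

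The interaction was the difference of nic1 nic2 myc2a from nic1 nic2 minus that of myc2a from K326. It was past the threshold in the positive direction for 84 gene models and in the negative direction for 17. Of these, 54 lay in the stretch of ID group 18, 6 in that of ID group 11, 22 in runs and 19 elsewhere (10 positive, 9 negative). An effect of the alleles cannot be told apart here from other differences between the lines. Outside these stretches, Ntab05g003880-1.1, chosen after its values were seen, had an interaction of 8.00 on the log2 scale (edgeR adjusted p = 1.25e-07). This gene model was nearly absent in myc2a alone (at most 0.244 CPM), outside any run. Its value cannot be told apart from a difference private to the myc2a line. For the set of 32 gene models the interaction was 0.66 (exact permutation p = 0.236; without K326 replicate 2, 0.33 with p = 0.44). Choosing the set for falls from K326 favours a positive value. For 28 gene models lower in both nic1 nic2 genotypes than in myc2a, 22 of them among the 32, it was -0.37 (exact permutation p = 0.32). Without K326 replicate 2 that value was -0.62 (exact permutation p = 0.0786). That choice favours a negative value, so the sign followed the choice of the set. DESeq2 gave 207 positive and 98 negative interactions. Without myc2a replicate 1 the count was 344, and without both K326 replicate 2 and nic1 nic2 replicate 3 it was 53.

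The myc2a and nic1 nic2 genotypes shared 5 calls against K326. Ntab20g021370-1.1, Ntab24g011880-1.1, Ntab09g011990-1.1 and Ntab11g000880-1.1 were higher, and Ntab11g025250-1.1, in the stretch of ID group 11, was lower. Ntab20g021370-1.1 was at 4.17 ± 0.989 CPM in K326 (SD, n = 4), 13.3 ± 3.95 in nic1 nic2 (n = 3), 15.4 ± 2.27 in myc2a (n = 5) and 19.7 ± 3.72 in nic1 nic2 myc2a (n = 4). The myc2a and nic1 nic2 myc2a genotypes shared 6 calls, 5 higher and 1 lower, among them the neighbours Ntab06g019810-1.1 and Ntab06g019820-1.1 and, lower, Ntab11g014000-1.1.

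Comparisons against the same K326 libraries share their chance values. For nic1 nic2 and myc2a, independent lists would share 0.0475 gene models higher and 0.342 lower, and simulated unchanged groups shared 0.05 on average and at most 1 in 20 simulations. With no gene model changed, these simulations do not give the overlap to be had by chance from lists of 395 and 73 calls. The covariance of log2 fold changes over gene models was 0.139 against a simulated 0.0944 to 0.105, but their correlation of 0.391 lay below the simulated mean of 0.478. With K326 split into separate pairs of libraries the median overlap was 1 over 6 splits, with only 2 K326 libraries per comparison. The covariance was still 0.0640 to 0.0928 with K326 split, with a median correlation of 0.173, so the shared K326 libraries did not account for all of the similarity. For nic1 nic2 and nic1 nic2 myc2a, with 52 shared calls, independent lists would share 0.166 higher and 0.452 lower. The covariance was 0.233 against a simulated 0.101, the correlation 0.516 against 0.451, and the split gave 22 to 25 shared calls and a covariance of 0.147 to 0.185. For myc2a and nic1 nic2 myc2a, with 6 shared calls, independent lists would share 0.016 higher and 0.107 lower, the covariance was 0.138 against a simulated 0.101, and the split gave a median of 1. Their correlation of 0.456 lay below the simulated 0.525. Without K326 replicate 2 and nic1 nic2 replicate 3 together the overlaps were 1, 33 and 1.

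Single libraries moved these overlaps by over 1.5 times. The overlap of nic1 nic2 and myc2a was 1 without K326 replicate 1, 2, 3 or 4, without nic1 nic2 replicate 3 or without myc2a replicate 2 or 3. It was 2 without nic1 nic2 replicate 2, myc2a replicate 5 or nic1 nic2 myc2a replicate 1, and 3 without myc2a replicate 4. The overlap of nic1 nic2 and nic1 nic2 myc2a was 30 without nic1 nic2 replicate 2 and 33 without nic1 nic2 replicate 3. The overlap of myc2a and nic1 nic2 myc2a was 2, 1, 2 and 3 without K326 replicates 1, 2, 3 and 4, 13 without myc2a replicate 1 and 11 without nic1 nic2 myc2a replicate 3.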

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

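The tests of explanations in this part, the splits of the samples included, were chosen after the results were seen, as were the stretches, the runs and the sets. Each group of 4 or 5 libraries was searched for a library far from the others. Of 51 groups of values, 7 held such a library. Chance gives about 1 in 20 for independent values that were not chosen on the same data. Some flagged values came from stretches that were defined by differences between these libraries, and several flags fell on the same library. The count therefore cannot be compared with that rate, and no excess over chance is claimed.

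K326 replicate 2 stood apart from the other K326 libraries in its total count (71.8 M against 36.1 M to 40.9 M), in its mean Spearman correlation to its own group (0.982 against 0.980 to 0.981) and in the summed level of the 32 gene models that fell in both nic1 nic2 genotypes (17047 CPM against 4970 to 6660). Among the myc2a libraries, replicate 4 was apart in the stretch of ID group 3 between 6500 and 10000 (154% of K326 against 99.9 to 110%), and replicate 1 in the stretch of ID group 11 (99.2% against 52.6 to 54.2%). The level of Ntab24g014140-1.1 in myc2a replicate 5 was 14.9 CPM (7.96 to 9.72 in the others), and that of Ntab19g019570-1.1 in myc2a replicate 4 was 10.1 CPM (8.29 to 8.76). The interaction tested whether the lines with and without myc2a differed alike in both backgrounds. It was past the threshold for 84 gene models in the positive and 17 in the negative direction, or 344 in all without myc2a replicate 1.

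For nic1 nic2 against K326, chance is argued against: 1 of 35 splits, the real one, gave 395 calls, and the highest other gave 0. This is the smallest share that 35 splits can give. The same holds for nic1 nic2 myc2a against K326 (1 of 35 splits; 127 calls, highest other 2) and against nic1 nic2 (1 of 35; 174, highest other 1). For myc2a against K326, 2 of 100 splits, the real one included, gave at least the real 73 calls (highest other 436). For nic1 nic2 myc2a against myc2a it was 4 of 100 (154 calls, highest other 1493). For the interaction, with the genotypes of all 16 libraries shuffled, it was 2 of 100 (84 positive and 17 negative calls, highest other 167). Few splits reached the real counts, but some exceeded them, so chance is not excluded for these comparisons. The splits with 436, 1493 and 167 calls kept myc2a replicates 2 to 5 together without replicate 1, and 409, 455 and 157 of their calls lay in the stretch of ID group 11. The split with 1493 calls only moved myc2a replicate 1 to the nic1 nic2 myc2a libraries, so it kept most of the real contrast, and 1023 of its calls lay outside the stretches. These splits point to a structure of the samples, with myc2a replicate 1 apart from the other myc2a libraries, and the stretch holds only part of it. By mean Spearman correlation to its own group, myc2a replicate 5 was the lowest of the myc2a libraries (0.953), below replicate 1 (0.962). A split with 1024 calls joined nic1 nic2 myc2a replicate 3 to myc2a replicates 2 to 5, with 842 calls outside the stretches, and 1 with 187 calls mixed both genotypes.

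The first pattern weighed is the level of 51.1 to 54.2% of K326 in the stretches of ID group 18 in nic1 nic2 and of ID group 11 in myc2a replicates 2 to 5. Scaling or depth is argued against, since no other ID group of these libraries had a median beyond 0.0593 on the log2 scale. At least 98.5% of each stretch was lower. The search needed shifted medians of 51 neighbours, so a few gene models could not have given a stretch, and this share is no separate test. That myc2a replicate 1 carries another genotype is argued against, since 0 of 15 gene models nearly absent in the other myc2a libraries reached 0.5 CPM in it. A candidate explanation is that 1 of 2 copies of the stretch was missing in these plants: the highest library median was 54.2%, inside bounds of 45 to 60% set after the values were seen. DNA was not analysed here, so this remains a hypothesis.

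The second pattern is the higher level of the 32 gene models in K326 replicate 2, at 2.86-fold the other K326 libraries, with 28 of 32 higher. Thinning to the depth of the others left the median log2 ratio at 1.52. Levels are already scaled to library size, so thinning could hardly move this ratio, and it does not decide on depth. A library of a recessive genotype is argued against, since it held 0.5 CPM or more of 100% of the 14, 10 and 13 gene models nearly absent in nic1 nic2, myc2a and nic1 nic2 myc2a that were called without it, outside the stretches. Of 5 gene models nearly absent in both nic1 nic2 genotypes, K326 replicate 2 was under 0.5 CPM in Ntab19g030530-1.1 (0.446 CPM). This was not particular to that library, since K326 replicate 1 was at 0.273 CPM in the same gene model. A difference in the plant or its time of collection stays open, and no biological explanation was tested.

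The third pattern is the runs of neighbouring gene models nearly absent in a single genotype. The alleles alone are argued against, since the runs nearly absent in nic1 nic2 and in myc2a were at 81.5% of K326 or more in nic1 nic2 myc2a. Scattered loss of single gene models is argued against for those in the runs only. Gene models nearly absent in a single genotype formed 7 (nic1 nic2), 5 (myc2a) and 4 (nic1 nic2 myc2a) neighbouring pairs. A permutation test with 10000 random draws of tested gene models gave at most 2 (p = 1e-04, the smallest they can give). The runs of ID groups 24, 8 and 19 held 8 of 14, 6 of 14 and 5 of 11 of these gene models. The others lay outside runs, so scattered loss stays open for them. A sequence difference from the reference that keeps reads from aligning and a deletion stay open, both untested.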

How the results depend on the processing

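Added after the data were seen were thinning K326 replicate 2, leaving it out with nic1 nic2 replicate 3, counting outside the stretches and runs, the overlaps that involve nic1 nic2 myc2a and, for every overlap, leaving out single libraries. Of the counts of calls and overlaps under the alternatives, 134 stayed within 1.5 times the reported value and 96 moved further; of the values of named genes, 15 were no longer past the threshold and 0 changed direction. The order of the comparisons below is nic1 nic2, myc2a and nic1 nic2 myc2a against K326, nic1 nic2 myc2a against nic1 nic2 and against myc2a, and interaction. DESeq2 called 1997, 248, 987, 638, 769 and 305, with overlaps of 31 (nic1 nic2 and myc2a), 308 (nic1 nic2 and nic1 nic2 myc2a) and 40 (myc2a and nic1 nic2 myc2a); the cause was not tested. Limma-voom gave 473 for myc2a, 1080 for nic1 nic2 myc2a against K326, 1220 against myc2a and 173 for the interaction; the cause was not tested. With only the compared groups, myc2a gave 43, nic1 nic2 myc2a 526 against K326, 68 against nic1 nic2 and 75 against myc2a; the cause was not tested. A factor for replicate number gave 36 for myc2a and 73 for nic1 nic2 myc2a against myc2a. Replicate numbers did not pair the libraries: over 21 pairs of equal number, the residual correlation had a median of -0.00759 (-0.21 to 0.18), and 3 of 16 libraries correlated best with their own number. Without K326 replicate 2 and nic1 nic2 replicate 3 together, nic1 nic2 gave 119, myc2a 22, nic1 nic2 myc2a against K326 82, the interaction 53 and the overlaps 1, 33 and 1, with fewer samples. Calls of at least 2-fold were 208 for nic1 nic2 and 47 for myc2a, with 2 shared. Outside the stretches and runs, 23 calls were left for myc2a, 60 for nic1 nic2 myc2a against nic1 nic2, 99 against myc2a and 19 for the interaction, by construction. At an adjusted p of 0.01 the overlaps were 1, 28 and 2, and with K326 split the medians were 1, 25 and 1. Leaving out each library gave 173 to 746, 19 to 434, 67 to 427, 126 to 291, 70 to 1132 and 76 to 344 calls, and overlaps of 1 to 6, 30 to 76 and 1 to 13. Over 26 alternatives, the medians, which have no test, stayed negative: that of the 32 gene models in myc2a (-0.98 with all libraries) ranged from -1.18 to -0.53, that of the stretch of ID group 11 from -0.97 to -0.65 and that of ID group 18 in nic1 nic2 from -0.97 to -0.86. The 21 gene lists and their tests were not run, since no identifier matched a symbol. In simulated data, 28 to 43% of 2-fold changes against K326 were recovered, which limits what a missing call says.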

Other observations

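The tests in this part were chosen after the results were seen. In ID group 7, between serial numbers 30 and 3070, the median of 151 gene models in nic1 nic2 replicate 3 was 59.2% of K326, with 93.4% of them lower, against 106 and 99.8% in nic1 nic2 replicates 1 and 2. In ID group 3, between 6500 and 10000, myc2a replicate 4 was at 154%, with 94.4% of 161 gene models higher. Both stretches were found in a single library each.

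A hypothesis is that both genotypes with nic1 nic2 lack the same stretches of genome. Of 5 gene models nearly absent in both, 2 lay near each other in ID group 7 (12920 to 12960; summed 5.72 ± 1.40 CPM in K326, n = 4, and 4.07 ± 1.22 in myc2a, n = 5) and 2 in ID group 19 (30530 to 30590; 1.56 ± 0.722 and 0.955 ± 0.295 CPM). The fifth was Ntab16g016700-1.1. Another tested gene model of the latter span, Ntab19g030580-1.1, was listed at 0 in both genotypes, with 0.339 CPM in K326 and no call (edgeR adjusted p = 0.159 and 0.177). The other gene models of both spans had too few counts to be tested. The 2 neighbouring pairs exceeded the at most 1 of a permutation test with 10000 random draws (p = 1e-04, the smallest they can give), which may reflect a shared missing stretch. Whether these places are the Nic loci was not analysed here, and a sequence difference from the reference stays open.

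A further hypothesis is that myc2a alone lowers the 32 gene models that fell with nic1 nic2. The test did not decide: the exact permutation p was 0.0159 with all libraries and 0.0536 without K326 replicate 2. The set was chosen for falls from the same K326 libraries, so neither p is independent. For 28 gene models lower in both nic1 nic2 genotypes than in myc2a, a choice that favours high values in myc2a, the mean log2 difference of myc2a from K326 was 0.19. Its exact permutation p was 0.516. The median of these gene models was -0.71, with 22 of 28 lower in myc2a. With gene models instead chosen on 2 K326 libraries and tested on the other 2, the median in myc2a lay between -0.31 and -1.84 over 6 splits. It was -0.31, -0.46 and -0.81 where K326 replicate 2 served for the choice, and -1.64, -1.73 and -1.84 where it served for the test. The size of the fall thus depended on this library.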
